A study of Mus musculus with 6 samples.

How the data were processed

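RNA was sequenced from the livers of C57BL/6J mice after a high-fat diet and 3 days of liraglutide or PBS, 3 libraries per group. Per the labels' protocols, the tissue was frozen on dry ice, total RNA was extracted with a column kit and libraries were made from it with Illumina's standard procedures. The authors deposited 1 table of raw read counts per gene, whole numbers that are not normalized, for 23412 gene symbols and 6 libraries. Per the submitters' processing notes, the STAR aligner and the mouse build mm10 were used. The counting tool, the annotation, the strand setting, the versions and the treatment of reads that match several genes are not given in the sources used here. Paralogs and genes that overlap on opposite strands may therefore share counts. Symbols are older than the annotation used for positions: 23011 matched 1 gene of GENCODE M21 (GRCm38, the same assembly as mm10), which supplied chromosome, start and end.

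Each column name carries its group and a number (Lira161, Lira162 and Lira164 for liraglutide, PBS155, PBS157 and PBS158 for PBS). Libraries are named here Lira or PBS with that number. It matches no triplicate number of the labels, so columns were assigned to groups only and the triplicate numbers were not tied to libraries. No 2 libraries were alike within sampling noise: the chi-square per degree of freedom of pairs within a group lay between 31.0 and 61.3, and Pearson's r of log2 CPM across genes between 0.984 and 0.989. The table holds 0 mitochondrially encoded genes, so that sign of RNA quality was not analysed here.

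Genes were kept by edgeR's filterByExpr on the groups, which left 12626 of the 16949 genes with at least 1 count. Counts were normalised by TMM factors and fitted with edgeR 4.0.16 in R 4.3.3 (estimateDisp, glmQLFit with robust estimation, glmQLFTest), with group as the only term. P-values are two-sided and adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. CPM are TMM-normalised, and log2 CPM for components and list levels used a prior count of 2. The common biological coefficient of variation was 0.157.

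The gene lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined. There were 45 lists with 873 distinct genes, textbook metabolic, stress, immune, clock and sex-biased liver genes and markers of cells a piece of liver can hold. In the table, 10 list genes were found under an older symbol and 25 were not found, among them all mitochondrially encoded genes, which leaves 44 lists, 41 of them with at least 5 tested members. Each list was given as counts of members past the threshold over all genes and adjusted over the list alone. Camera, with a preset correlation of 0.01 and with an estimated correlation, and fry were run from limma 3.58.1 on the edgeR fit, adjusted over the 41 lists. The level of a list in a library is the mean over its tested members of log2 CPM minus the mean of the PBS libraries.

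The named genes were the 10 with the largest log2 fold change in each direction among changed genes with a mean CPM of at least 5 and groups that did not overlap (432 higher and 506 lower genes qualified). For each list up to 4 called members with the smallest p were added, or 2 members given as values where none was called, and a fixed set of metabolic genes was given as values in any case. Some genes that met these rules are not reported here. Where a count of 5 or fewer left out a member, it was named after its values were seen: Thrsp, Me1, Dgat2, Baat, Akr1d1 and Gpi1, and for their overlap Txnip and Nt5dc2.

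The procedure was tested on simulated counts with the means and library sizes of the comparison of liraglutide with PBS, with 200 genes changed among 12510 tested. It recovered 23.9% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 95.5% of those changed 4-fold, with 6 false among 132 calls. A planted list of 20 genes shifted by 0.5 on the log2 scale had a camera adjusted p of 6.27e-15, and 0 of 40 unshifted lists were called. Simulated genes varied independently of each other and lists were drawn at random. The simulation therefore does not show how camera's preset correlation fares on lists whose members move together. In the real lists the estimated correlation lay between -0.086 (T and natural killer cells) and 0.865 (ribosomal proteins).

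Alternatives were DESeq2 size factors, upper quartile factors or library totals in the same fit, no filter beyond 1 count, a filter at a mean CPM of 5, the Wald test of DESeq2 1.42.0 with its default filtering, limma-voom, removal of the 10 most abundant genes, and each library left out in turn. Library totals between 20888991 and 27007182 counts limit the precision of low genes. Confidence intervals of shares are exact Clopper-Pearson intervals at 95%, and a count of 0 is taken to allow up to 3 counts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.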

Results

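Transcripts were measured by RNA sequencing in 6 liver libraries from C57BL/6J mice, a common inbred strain, labelled as 8 weeks of age. After 4 weeks on a diet rich in fat they were treated under the skin over 3 days, liraglutide at 300 µg/kg in 3 libraries and phosphate-buffered saline (PBS) in the other 3. Liraglutide is an agonist of the receptor for glucagon-like peptide 1, a gut hormone that raises insulin secretion and lowers food intake. The comparison asked which liver transcripts differed after short liraglutide treatment on this diet. With liraglutide and PBS as the only groups, changes that follow from lower food intake cannot be told apart from other effects of the drug. Total counts were 20888991, 25404192 and 23079721 in libraries Lira161, Lira162 and Lira164, and 27007182, 23693957 and 21901811 in libraries PBS155, PBS157 and PBS158. Each library is named by its group and the number of its column in the count table, and means are over 3 libraries per group. The labels do not say that the replicates were separate animals, so p-values measure the spread between these libraries, which may be technical.

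After liraglutide, most tested genes of cholesterol synthesis were lower, and PPAR-alpha targets and genes of fatty acid oxidation were higher where they changed. Of 25 tested genes of cholesterol synthesis and SREBP-2 control, 22 fell and none rose, with a median log2 fold change of -1.87. Of 30 tested PPAR-alpha targets and fatty acid oxidation genes, 13 rose and none fell, with a median of 0.51. Scd1, the stearoyl-CoA desaturase, was 20.3-fold lower (log2 fold change -4.34 ± 0.38, SE), and Fgf21, a liver hormone of the fasting response, was 8.57-fold higher (3.10 ± 0.27). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 6.51-fold lower (-2.70 ± 0.34).

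In all, 1107 of 12626 tested genes (8.77%) changed at an adjusted p below 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 515 higher and 592 lower under liraglutide. Among them 383 changed by at least 1 on the log2 scale, 180 higher and 203 lower. With library totals in place of TMM factors, 57.2% of the changed genes were higher, against 46.5% with TMM. The groups did not overlap for 3951 tested genes (31.3%), where chance gives 10%, and for all of the 1107 changed genes. The first principal component of the 500 most variable genes held 67.2% of their variance and placed libraries Lira161, Lira162 and Lira164 at 19.2, 27.1 and 10.3 and libraries PBS155, PBS157 and PBS158 at -17.7, -16.7 and -22.3. The number of changed genes moved with the libraries used: it was 462, 393 and 1496 without library Lira161, Lira162 or Lira164, and 962, 653 and 414 without library PBS155, PBS157 or PBS158.

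**Figure D1:**
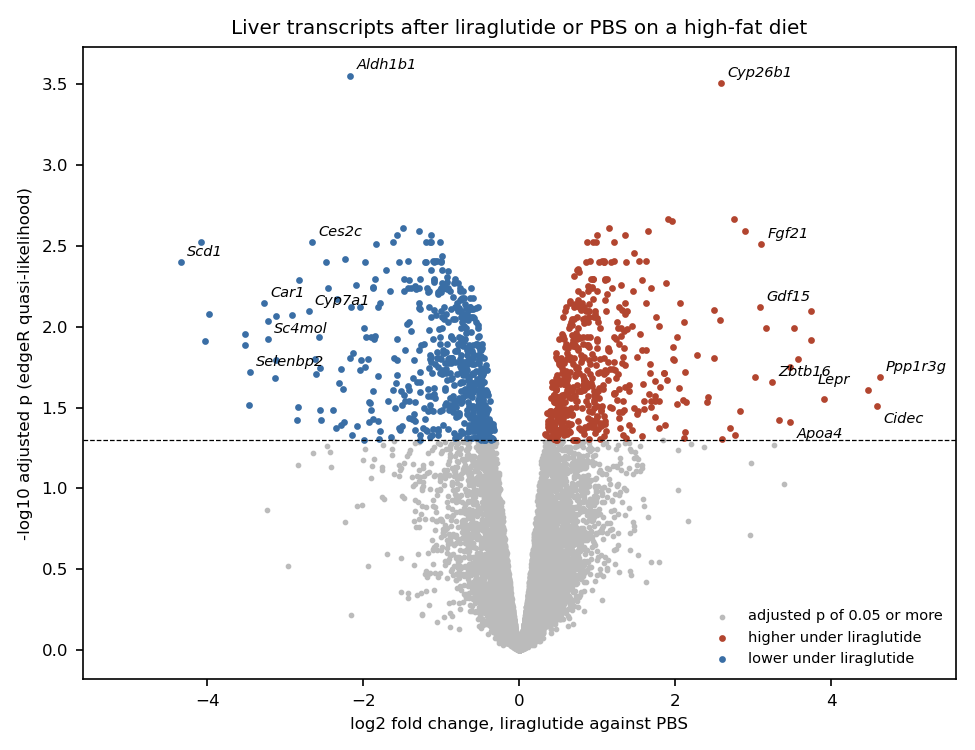
Each point is 1 of 12626 tested genes, with the log2 fold change of liraglutide against PBS on the x axis and the -log10 adjusted p of the edgeR quasi-likelihood test on the y axis; the dashed line marks 0.05. Genes above the line are coloured, 515 higher and 592 lower, and Scd1 lies farthest left among the labelled genes, at -4.34.

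The 10 genes that rose most, among those with a mean of at least 5 CPM (counts scaled to a common library size) and groups that did not overlap, were led by Ppp1r3g, a glycogen-targeting subunit of protein phosphatase 1 (chromosome 13, 35958839 to 35970388, GRCm38), at 29.4 ± 6.14 CPM (SD) against 1.17 ± 1.18 (log2 fold change 4.62 ± 0.70, adjusted p = 0.0205). Cidec, a lipid droplet protein (chromosome 6, 113424634 to 113435760), was at 189.7 ± 107 against 7.92 ± 5.09 CPM (4.58 ± 0.77, adjusted p = 0.0310). Lepr, the leptin receptor (chromosome 4, 101717404 to 101815352), was at 149 ± 104 against 6.72 ± 2.95 CPM (4.47 ± 0.69, adjusted p = 0.0246). Apoa4, an apolipoprotein (chromosome 9, 46240696 to 46243459), was at 10285 ± 6423 against 928 ± 371 CPM (3.47 ± 0.68, adjusted p = 0.0387). Fgf21 (chromosome 7, 45613886 to 45615490) was at 48.7 ± 14.5 against 5.68 ± 1.25 CPM (adjusted p = 0.00309). Cgref1, Cntnap1, Agap2 and Zbtb16 rose by log2 fold changes of 3.58, 3.46, 3.33 and 3.24. The predicted gene Gm15441 rose by 3.52 but overlaps exons of Txnip on the opposite strand by 441 bp, and Txnip itself was higher by 1.48 (adjusted p = 0.00351). The strand setting of the counting is not given in the sources used here, so reads within the overlap cannot be assigned to either gene. The 441 bp are the longest overlap of single exons, and the exons of Gm15441 cover 1676 bp.

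Scd1 (chromosome 19, 44394455 to 44407879) led the 10 genes that fell most, at 32.0 ± 12.6 CPM under liraglutide against 649 ± 190.4 under PBS (adjusted p = 0.00399). Among them were Mvd, Sc4mol (now Msmo1), Sqle and Idi1, enzymes of cholesterol synthesis, with log2 fold changes of -3.47, -3.23, -3.14 and -3.12. Cyp7a1 (chromosome 4, 6265612 to 6275633) was at 80.0 ± 25.6 against 521 ± 171 CPM (adjusted p = 0.0080). Selenbp2 was at 32.1 ± 18.8 against 351 ± 18.3 CPM (-3.45 ± 0.51), Car1, a carbonic anhydrase, at 0.99 ± 0.77 against 9.61 ± 1.59 (-3.27 ± 0.44) and Ces2c, a carboxylesterase, at 3.06 ± 1.17 against 19.2 ± 1.88 (-2.66 ± 0.26). Selenbp2 and Ces2c have close paralogs whose reads could be shared, so their values are uncertain. Of the 20 genes with the largest changes in either direction, Fgf21, Scd1, Car1, Cyp7a1 and Ces2c kept an adjusted p below 0.05 whichever library was left out. The call held for 10, 10 and 16 of the 20 without library Lira161, Lira162 or Lira164 and for 7, 13 and 11 without library PBS155, PBS157 or PBS158. Without the low-count filter 13 of the 20 kept it.

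**Figure D2:**
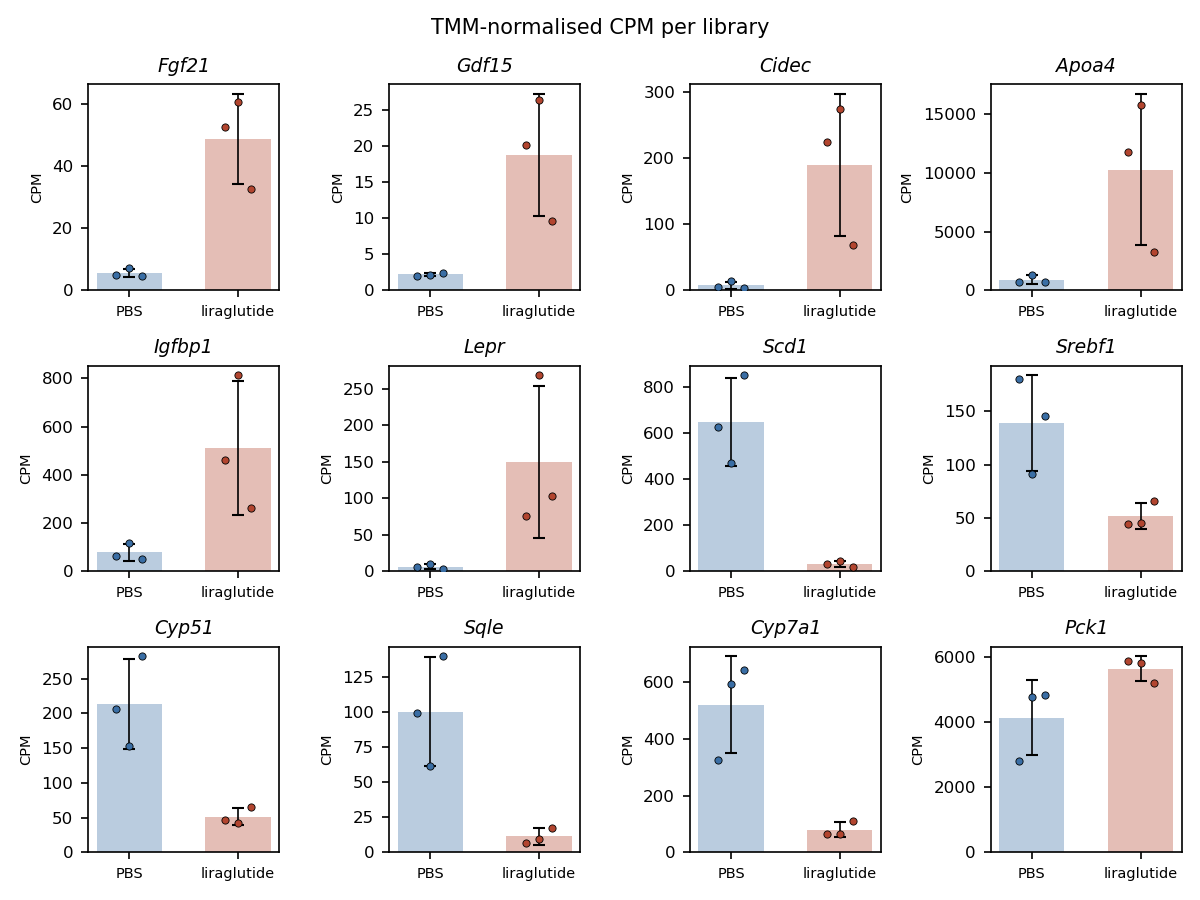
Bars give the mean TMM-normalised CPM of 12 genes in 3 PBS and 3 liraglutide libraries, error bars the SD and points the single libraries; each panel has its own y axis, starting at 0. Fgf21 lies at 48.7 CPM under liraglutide and 5.68 under PBS, Scd1 at 32.0 and 649, and for Pck1 the means are 5648 and 4142 with an adjusted p of 0.204.

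In cholesterol synthesis 22 of 25 members passed, the largest share among the gene lists. Tm7sf2 (-1.57 ± 0.16), Dhcr7 (-1.28 ± 0.16) and Cyp51 (-2.05 ± 0.26), all enzymes of sterol synthesis, fell, with edgeR adjusted p between 0.00273 and 0.00758. Tm7sf2 overlaps exons of Vps51 by 532 bp on the same strand, so its value is uncertain. Adjusted over the list alone, 24 of the 25 members were lower. The competitive test camera gave adjusted p = 5.43e-41 with its preset correlation between genes and adjusted p = 0.282 with an estimated correlation. The count of 22 was 8, 6 and 21 without library Lira161, Lira162 or Lira164, 11, 23 and 16 without library PBS155, PBS157 or PBS158, and 13 without the low-count filter. The mean log2 level of the list relative to PBS was -2.03, -1.92 and -1.45 in libraries Lira161, Lira162 and Lira164, and 0.053, -0.494 and 0.441 in libraries PBS155, PBS157 and PBS158.

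Genes of fatty acid synthesis moved in both directions. Of 19 tested, 4 fell and 3 rose; adjusted over the list alone 7 were lower and 4 higher (camera adjusted p = 0.0654 and 0.575 with an estimated correlation). Besides Scd1, the acetyl-CoA synthetase gene Acss2 fell by 0.98 ± 0.14 and Srebf1, the transcription factor of the pathway, fell from 139 ± 44.9 to 51.9 ± 11.8 CPM (-1.42 ± 0.28, adjusted p = 0.0287). Thrsp also fell (-2.39). Acacb, whose product makes the malonyl-CoA that restrains fatty acid oxidation, rose by 1.69 ± 0.21. The elongase gene Elovl5 rose by 1.00 ± 0.16 and Me1 by 0.55. Fasn, the fatty acid synthase gene, was at 86.2 ± 12.6 against 168 ± 61.5 CPM (-0.96 ± 0.29, adjusted p = 0.0947). Leaving out libraries Lira161, Lira162, Lira164, PBS155, PBS157 and PBS158 in turn gave 2, 3, 4, 2, 5 and 2 lower members, and no low-count filter gave 2; camera called the list without PBS157 (adjusted p = 0.000152) and without the filter (0.0296). Srebf1 lost its call without Lira161, Lira162, PBS155 or PBS158, at adjusted p up to 0.115, and Fasn was called without PBS157 (adjusted p = 0.00446) and with DESeq2 (0.00107).

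PPAR-alpha targets and fatty acid oxidation genes were higher where they changed, 13 of 30. This list also holds targets that are not enzymes of oxidation, such as Fgf21, Plin2 and Cidec. Plin2 and Cidec were both called and also stand in the lipid droplet list. Beside Fgf21, Acot1, an acyl-CoA thioesterase, was at 278 ± 27.5 against 96.0 ± 24.3 CPM (1.54 ± 0.18, adjusted p = 0.00391), and Pdk4, a kinase that restrains pyruvate oxidation, at 30.1 ± 13.8 against 5.06 ± 0.82 (2.57 ± 0.34, adjusted p = 0.00908). Cpt1a, the gate of fatty acid entry into mitochondria, rose from 1009 ± 82.7 to 1476 ± 140.2 CPM (0.55 ± 0.13, adjusted p = 0.0288), while Ppara itself was at 666 ± 38.4 against 613 ± 81.5 CPM (0.12 ± 0.13, adjusted p = 0.594). Adjusted over the list alone, 21 of 30 members were higher. For this list camera gave adjusted p = 4.34e-15, against adjusted p = 0.241 with an estimated correlation. The 13 higher members became 6, 5 and 12 without library Lira161, Lira162 or Lira164 and 5, 9 and 7 without PBS155, PBS157 or PBS158. Cpt1a was called only without Lira164 among these fits (adjusted p up to 0.111).

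Lipid droplet genes were mostly higher where they changed. Of 21 tested members, 10 rose and 1 fell, and adjusted over the list alone 12 were higher and 1 lower (camera adjusted p = 6.02e-08; adjusted p = 0.241 with an estimated correlation). The droplet coat gene Plin2 rose from 721 ± 75.2 to 1473 ± 333 CPM (1.03 ± 0.18, adjusted p = 0.0102). Hilpda (2.28 ± 0.40) and G0s2 (1.67 ± 0.29), whose products inhibit lipolysis, and Mgll (0.51 ± 0.10), a monoglyceride lipase gene, also rose, and Dgat2, a gene of triglyceride synthesis, was the member that fell (-0.53). Leaving out libraries Lira161, Lira162, Lira164, PBS155, PBS157 and PBS158 in turn left 2, 3, 13, 4, 4 and 2 higher members, and Dgat2 was not called with library totals as the scaling or without Lira161, Lira162, PBS155 or PBS158. Hilpda lost its call without PBS155 or PBS158, G0s2 without Lira161, Lira162 or PBS158 and Mgll without Lira161, Lira162, PBS157 or PBS158, at adjusted p up to 0.0775. Cd36, a fatty acid carrier gene, was at 55.7 ± 13.8 against 41.7 ± 11.8 CPM (adjusted p = 0.362) and Pparg at 12.1 ± 1.09 against 11.0 ± 0.56 (adjusted p = 0.515). Cidea had between 1 and 7 counts per library and was not tested. Of 22 lipoprotein genes, Apoa4 and Apoa5 (0.65 ± 0.13) rose and 1 fell, with 2 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.885). In the same order of left-out libraries these counts were 0, 0, 4, 1, 0 and 1 higher and 0, 0, 4, 0, 2 and 1 lower, and 1 was higher without the low-count filter. Apoa5 lost its call without Lira161, Lira162 or PBS157 (adjusted p up to 0.0697), and Apoa4 kept its call only without Lira164.

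Genes of glucose output changed in few cases. Of 21 gluconeogenesis and fasting genes, Igfbp1, Gadd45b and Pcx rose and none fell, 3 and 1 when adjusted over the list alone (camera adjusted p = 0.0546; adjusted p = 0.574 with an estimated correlation). Igfbp1, which codes for a secreted protein that binds insulin-like growth factors, was at 511 ± 279 against 78.5 ± 35.4 CPM (2.70 ± 0.54, adjusted p = 0.0420), Gadd45b at 13.8 ± 7.44 against 2.09 ± 1.48 and Pcx, the pyruvate carboxylase gene, at 953 ± 56.1 against 694 ± 76.0. The gluconeogenic genes Pck1 (0.45 ± 0.20, adjusted p = 0.204) and G6pc (0.75 ± 0.24, adjusted p = 0.0921) did not pass the test. G6pc passed with DESeq2 (adjusted p = 0.00589). Without libraries Lira161, Lira162, Lira164, PBS155, PBS157 and PBS158 in turn the list had 0, 0, 5, 1, 0 and 1 higher members, and it had 1 without the low-count filter or without the 10 most abundant genes. Pcx was called in none of the 6 fits with a library left out (adjusted p up to 0.177), Igfbp1 only without Lira164 (otherwise up to 0.132) and Gadd45b only without PBS158 (otherwise up to 0.157). Camera called the list without Lira164, PBS157 or PBS158 (adjusted p = 0.00897, 0.0263 and 0.0165), without the filter (0.0256) and without the abundant genes (0.0486). Among 21 insulin and glucagon signalling genes, Lpin2 (1.11 ± 0.18), Igfbp2 (1.00 ± 0.20) and Igfbp1 rose and Sort1 fell (-0.84 ± 0.18), with 3 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.211). Their leave-one-out counts, in that order, were 1, 1, 4, 2, 3 and 1 higher and 0, 1, 3, 1, 1 and 0 lower. Sort1 lost its call without Lira161, PBS155, PBS157 or PBS158 (adjusted p up to 0.0849) and Igfbp2 without Lira161, Lira162 or PBS158 (up to 0.0801). Gcgr, the glucagon receptor gene, was at 360.3 ± 40.2 against 319 ± 35.5 CPM (0.18 ± 0.13, adjusted p = 0.426), and Irs2 at 26.8 ± 16.4 against 18.0 ± 4.20 (0.57 ± 0.45, adjusted p = 0.488; -0.07 without library Lira164).

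For glycogen and sugar breakdown, 4 of 21 tested members rose and 1 fell. Gys2, the liver glycogen synthase gene, rose from 312 ± 37.2 to 592 ± 35.7 CPM (0.92 ± 0.12, adjusted p = 0.00508), Gpi1 rose by 0.44, next to Ppp1r3g, and Khk, the ketohexokinase gene, fell by 0.65 ± 0.14. Adjusted over the list alone 4 were higher and 1 lower, and camera gave adjusted p = 0.913; the median of the list was -0.14 and its mean 0.086. Leaving out libraries Lira161, Lira162, Lira164, PBS155, PBS157 and PBS158 gave 1, 1, 3, 2, 3 and 3 higher and 0, 0, 1, 1, 3 and 0 lower members. Khk lost its call without Lira161, Lira162 or PBS158 (adjusted p up to 0.101).

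Bile acid genes were mostly lower where they changed. Of 24 tested members, 5 fell (Cyp7a1, Slc27a5, Abcb11, Baat and Akr1d1) and 1 rose (Abcb4), and adjusted over the list alone 7 were lower and 2 higher (camera adjusted p = 0.00204; adjusted p = 0.475 with an estimated correlation). Slc27a5 and Baat, which conjugate bile acids, changed by -0.67 ± 0.11 and -0.56, the bile salt export pump gene Abcb11 by -0.64 ± 0.14, Akr1d1 by -1.93 and the phospholipid exporter gene Abcb4 by 0.75 ± 0.13. Cyp8b1 was at 995 ± 268 against 680.3 ± 125 CPM (0.55 ± 0.21, adjusted p = 0.147). It was called without Lira164 (adjusted p = 0.0254) and with DESeq2 (0.0479). With Lira161, Lira162, Lira164, PBS155, PBS157 and PBS158 left out in turn, 3, 2, 7, 5, 3 and 2 members were lower and 2, 1, 3, 1, 1 and 0 higher. Abcb11 lost its call without Lira162 or PBS158 (adjusted p up to 0.0716) and Abcb4 without PBS158 (0.0517). Of 14 targets of CAR and PXR, nuclear receptors that control drug metabolism, Ces2a (-1.46 ± 0.29) and Gstm3 (-1.55 ± 0.39) fell and Por rose (0.74 ± 0.17), with 2 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.0637 and 0.575 with an estimated correlation). In the same order 0, 1, 2, 0, 1 and 0 of them were lower and 0, 0, 2, 0, 1 and 0 higher, and 1 was lower without the low-count filter. Camera called this list without Lira162, Lira164, PBS155 or PBS157 (adjusted p = 0.0373, 0.00413, 0.0215 and 0.00938) and without the filter (0.0375). Gstm3 was called only without PBS157, Ces2a only without Lira162 or Lira164 and Por only without Lira164 or PBS157 (otherwise adjusted p up to 0.123).

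Among 24 genes of the urea cycle and amino acid breakdown 6 fell and none rose, and adjusted over the list alone 6 were lower and 2 higher (camera adjusted p = 0.0295; adjusted p = 0.577 with an estimated correlation). Gls2, a glutaminase gene, fell by 1.01 ± 0.12, the proline dehydrogenase gene Prodh by 1.09 ± 0.14 and the histidine ammonia-lyase gene Hal by 0.79 ± 0.15. The 6 became 3, 3, 5, 6, 5 and 2 without libraries Lira161, Lira162, Lira164, PBS155, PBS157 and PBS158, 5 rose without Lira164, and the camera call was lost without Lira164 or PBS158 (adjusted p = 0.56 and 0.145) and with limma-voom (0.0517). Hal lost its call without Lira162 or PBS158. Of 20 genes that mark hepatocytes near the central vein, 7 fell and 1 rose, adjusted over the list alone 9 and 3 (camera adjusted p = 0.000514; adjusted p = 0.45 with an estimated correlation). Besides Cyp7a1, they include the aldehyde dehydrogenase gene Aldh1a1 (-1.01 ± 0.19) and the ammonium transporter gene Rhbg (-1.12 ± 0.23), with the amino acid transporter gene Slc16a10 higher (0.60 ± 0.09). In the order above, 2, 3, 8, 3, 5 and 2 of them were lower. Aldh1a1 lost its call without Lira161, Lira162 or PBS158 (adjusted p up to 0.0777) and Rhbg without Lira162 or PBS157 (up to 0.0751). Of 22 genes of hepatocytes near the portal vein, 5 fell, among them Gls2, Cyp2f2 (-0.88 ± 0.15), Hal and Pigr (-0.86 ± 0.17), and 3 rose, among them Apoa4 and Hamp, with 5 higher and 6 lower when adjusted over the list alone. Camera gave adjusted p = 0.928 for a direction downward although the list's median was 0.20, and the left-out libraries gave 3, 2, 5, 4, 4 and 3 lower and 0, 0, 7, 1, 1 and 2 higher members. Pigr lost its call without Lira161, Lira162 or PBS158 (adjusted p up to 0.0669).

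Stress responses differed by kind. Of 19 tested genes of the integrated stress response, which slows translation, Fgf21 and Gdf15 rose, Gdf15 from 2.20 ± 0.24 to 18.7 ± 8.44 CPM (3.09 ± 0.39, adjusted p = 0.00757). Adjusted over the list alone 7 were higher and 1 lower (camera adjusted p = 0.000425; adjusted p = 0.478 with an estimated correlation), and 5 and 3 passed over all genes without library Lira164 or PBS157. Of 22 genes of the unfolded protein response and endoplasmic reticulum chaperones, 7 fell and none rose, adjusted over the list alone 11 and 1 (camera adjusted p = 3.19e-05; adjusted p = 0.497 with an estimated correlation). The protein disulfide isomerase genes Pdia4 and Pdia6 fell by 0.62 ± 0.11 and 0.73 ± 0.15, and the cochaperone genes Dnajb11 and Sdf2l1 by 0.46 ± 0.10 and 1.31 ± 0.26. Without libraries Lira161, Lira162, Lira164, PBS155, PBS157 and PBS158 this count was 0, 1, 11, 5, 2 and 2. Pdia4 lost its call without Lira161 (adjusted p = 0.0508), Pdia6 without Lira161, Lira162 or PBS158, Dnajb11 without Lira161, Lira162, PBS157 or PBS158 and Sdf2l1 without Lira161, Lira162, PBS155 or PBS157 (up to 0.0933). Cytosolic heat shock genes went the other way where they changed: 9 of 19 rose and none fell, 12 when adjusted over the list alone (camera adjusted p = 5.81e-07; adjusted p = 0.319 with an estimated correlation). Hspa1b rose by 1.35 ± 0.21, Hsp90aa1 by 0.84 ± 0.14, Hsph1 by 0.82 ± 0.14 and Bag3 by 0.51 ± 0.09, and the left-out libraries gave 6, 4, 7, 6, 9 and 5 higher members. Bag3 lost its call without Lira162 (adjusted p = 0.0565). Of 16 immediate early genes, which tissue handling can raise, 7 rose in the same libraries. Levels summed over the whole list, scaled to library totals without TMM factors, were 528, 539 and 516 CPM against 348, 251 and 282. Among 20 NRF2 targets, genes of the oxidative stress response, Gsta4, Sod2 and Gstm3 fell (-0.60 ± 0.11, -0.36 ± 0.09 and -1.55 ± 0.39) and none rose, with 1 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.491), and 0, 0, 3, 1, 2 and 0 were lower in the order above. Gsta4 lost its call without Lira161, Lira162 or PBS158, and Sod2 kept its call only without Lira164 (otherwise adjusted p up to 0.159). Of 24 autophagy and lysosome genes, Lipa rose (0.48 ± 0.13) and Atg5 fell (-0.35 ± 0.09), with 4 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.192). Lipa was called only without Lira164 and Atg5 only without PBS155 when libraries were left out.

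**Figure D3:**
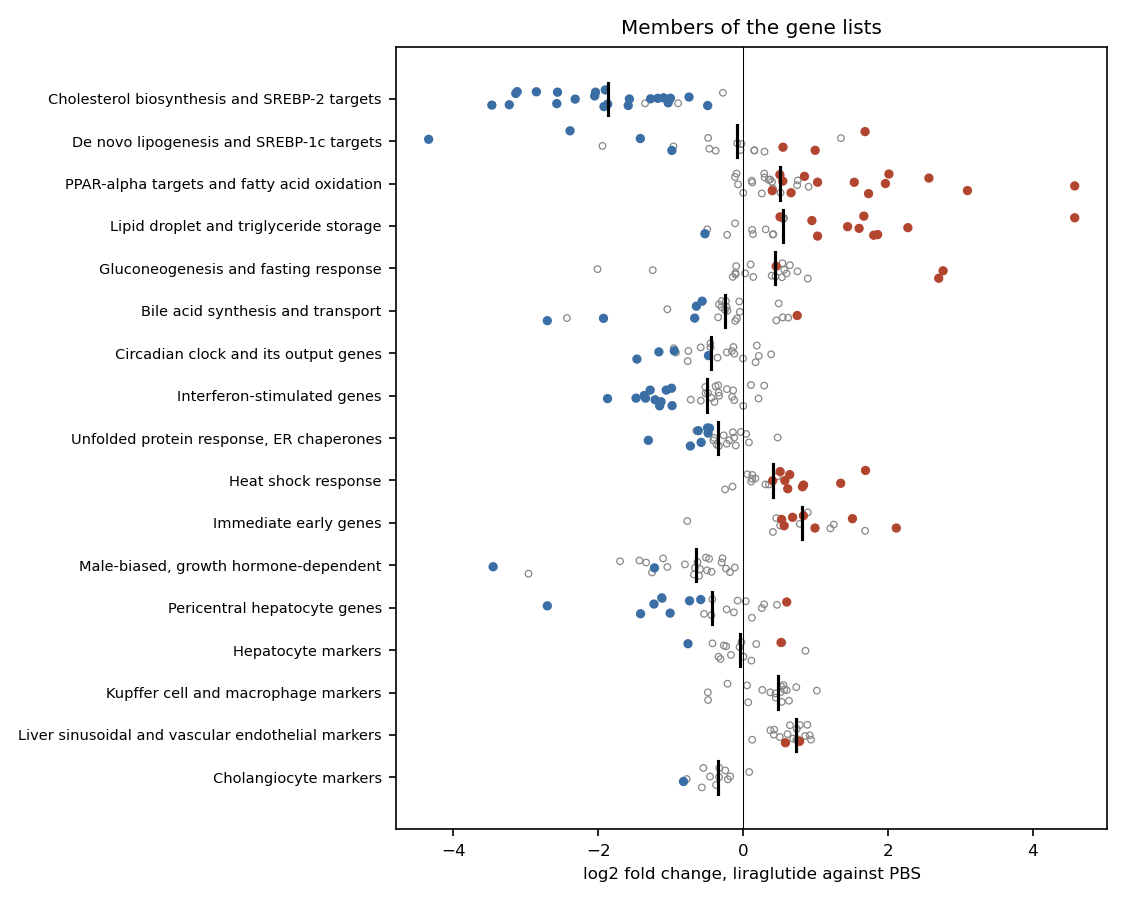
Each point is a tested gene of 1 of 17 gene lists, placed by its log2 fold change of liraglutide against PBS; filled points passed an adjusted p of 0.05 (red higher, blue lower), open points did not, and the black bar is the median of the list. The bar lies at -1.87 for cholesterol synthesis, 0.51 for PPAR-alpha targets and fatty acid oxidation, and -0.05 for hepatocyte markers.

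Circadian clock genes were lower where they changed. Of 21 tested, 4 fell and none rose, and adjusted over the list alone 8 were lower (camera adjusted p = 3.19e-05; adjusted p = 0.497 with an estimated correlation). They were Ccrn4l (now Noct; -0.95 ± 0.13), the repressor genes Cry1 (-1.16 ± 0.20) and Cry2 (-0.48 ± 0.12) and Per3, which fell from 58.7 ± 6.42 to 21.3 ± 7.31 CPM (-1.47 ± 0.24, adjusted p = 0.0139). Nr1d1, another clock repressor gene, was at 104 ± 13.2 against 114 ± 13.3 CPM (-0.13 ± 0.13, adjusted p = 0.545), and Dbp, a clock output gene, at 105 ± 38.05 against 176 ± 10.04 (-0.75 ± 0.25, adjusted p = 0.110). Dbp, which overlaps exons of Sphk2 by 539 bp and is therefore uncertain, passed without Lira164 (adjusted p = 0.00555) and with DESeq2 (0.00802). The 4 became 2, 4, 10, 3, 3 and 2 without libraries Lira161, Lira162, Lira164, PBS155, PBS157 and PBS158, and 9 with DESeq2. Cry2 was called only without Lira164 (otherwise adjusted p up to 0.152), and Per3 lost its call without Lira161 or PBS158 (up to 0.0625). Of 17 glucocorticoid receptor targets, Zbtb16, at 83.5 ± 25.7 against 8.93 ± 4.83 CPM, was the only 1 that rose, with 3 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.415). The left-out libraries gave 0, 0, 3, 3, 0 and 1 higher members, and 4 fell without Lira164 and 1 without PBS157. Zbtb16 lost its call without Lira161, Lira162 or PBS157 (adjusted p up to 0.0991). Among 24 male-biased genes that depend on growth hormone, Ugt2b1 (-1.22 ± 0.21) and Selenbp2 fell, and the median was -0.65 (camera adjusted p = 2.51e-07; adjusted p = 0.497 with an estimated correlation), with the same 2 lower when adjusted over the list alone. The Mup genes in this list share nearly identical sequence, so their counts are uncertain, and 4, 2, 4, 3, 1 and 1 members were lower with a library left out, and 7 with DESeq2. Selenbp2 lost its call without Lira161, PBS155, PBS157 or PBS158 (adjusted p up to 0.0716). Of 10 female-biased genes, A1bg rose from 0.11 ± 0.07 to 1.58 ± 1.04 CPM (3.74 ± 0.67, adjusted p = 0.0121), with 2 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.17). The call of A1bg was lost without PBS158 (adjusted p = 0.0567), and camera called the list without Lira161 or PBS158 (0.00285 and 0.0339).

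Interferon-stimulated genes were lower where they changed. Of 30 tested, 11 fell and none rose, 14 when adjusted over the list alone (camera adjusted p = 1.72e-10; adjusted p = 0.45 with an estimated correlation). Ifit1 fell from 39.6 ± 7.26 to 10.8 ± 2.96 CPM (-1.87 ± 0.23, adjusted p = 0.00573), and Isg15 (-1.28 ± 0.18), I830012O16Rik (now Ifit3b; -1.48 ± 0.21) and Rsad2 (-1.13 ± 0.18) fell as well. Without libraries Lira161, Lira162, Lira164, PBS155, PBS157 and PBS158 the count was 5, 6, 16, 11, 9 and 5. Other inflammatory genes changed singly. Vcam1, an adhesion molecule gene, and Ccl5, a chemokine gene, rose among 16 (1.17 ± 0.14 and 1.57 ± 0.41; camera adjusted p = 0.192), 2 also when adjusted over the list alone, but Ccl5 kept the call only without Lira164. Camera called this list without PBS155 (adjusted p = 0.0215) and with a mean CPM of at least 5 (0.0498). Hamp, the gene of the iron hormone hepcidin, rose among 25 acute phase genes, from 505 ± 167 to 1165 ± 135 CPM (1.21 ± 0.23, adjusted p = 0.0183; camera adjusted p = 0.161), 1 also when adjusted over the list alone, and lost the call without Lira161, Lira162 or PBS155 (adjusted p up to 0.0779). Camera called the acute phase list, downward, without Lira161 or PBS155 (adjusted p = 0.00347 and 0.0366). Ccl2 had between 4 and 10 counts per library and was not tested. Of 22 extracellular matrix genes, the basement membrane collagen genes Col4a1 (1.09 ± 0.13) and Col4a2 (0.64 ± 0.11) rose and Spp1 fell (-0.82 ± 0.11), with 2 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.192; 0.0422 without Lira161 and 0.049 without PBS157). Exons of Col4a1 and Col4a2 overlap by 22 bp. Col1a1, of fibrillar collagen, was at 2.93 ± 1.72 against 4.08 ± 2.94 CPM (adjusted p = 0.679).

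Few markers of other liver cells passed the test singly. Of 19 endothelial markers, Clec4g (0.78 ± 0.17) and Stab1 (0.59 ± 0.13) rose, 11 when adjusted over the list alone, and the median was 0.74 (camera adjusted p = 3.67e-07; adjusted p = 0.497 with an estimated correlation). Without libraries Lira161, Lira162, Lira164, PBS155, PBS157 and PBS158 the number higher was 2, 0, 1, 13, 0 and 0, and it was 9 with DESeq2. Clec4g lost its call without Lira161, Lira162, PBS157 or PBS158 and Stab1 without Lira162, Lira164, PBS157 or PBS158 (adjusted p up to 0.108). The mean endothelial level relative to PBS was 0.319, 0.746 and 0.97 in libraries Lira161, Lira162 and Lira164, 0.466 in library PBS155 and -0.201 and -0.265 in libraries PBS157 and PBS158. Stab1 overlaps exons of Nt5dc2 on the opposite strand by 112 bp, and Nt5dc2 was higher by 1.36. No Kupffer cell marker of 18 passed the test, and none did when adjusted over the list alone (camera adjusted p = 0.056); Cd163 was at 20.2 ± 2.32 against 9.91 ± 4.51 CPM (adjusted p = 0.0793) and Slc40a1 at 115 ± 17.5 against 161.2 ± 24.6 (adjusted p = 0.0717). Cd163 passed without PBS155 (adjusted p = 0.00543), with limma-voom (0.039) and with DESeq2 (0.00192). Slc40a1 passed without Lira164 (0.021) and with DESeq2 (0.0263). Without PBS155, 6 Kupffer markers were higher (camera adjusted p = 1.88e-12), and camera also called the list without Lira162 (0.00261), without the filter (0.0232), with limma-voom (0.0332) and without the 10 most abundant genes (0.0419). For this list adjusted p = 0.726 with an estimated correlation. The Kupffer level was 1.00 in library PBS155, -0.215 in PBS157 and -0.787 in PBS158, against 0.698, 0.211 and 0.775 in libraries Lira161, Lira162 and Lira164. Of 17 stellate cell markers, Vipr1 rose (0.69 ± 0.11), 3 when adjusted over the list alone (camera adjusted p = 0.00244; adjusted p = 0.574 with an estimated correlation), and 5 passed without library PBS155. Of 12 cholangiocyte markers, Spp1 fell, the only 1 also when adjusted over the list alone, and the median was -0.35 (camera adjusted p = 0.0366; adjusted p = 0.497 with an estimated correlation). That call was lost without Lira161, Lira162 or PBS155 (adjusted p = 0.0737, 0.0555 and 0.124). Hepatocyte markers, 15 in number, had a median of -0.05, with Hnf4a higher (0.53 ± 0.13) and Serpina1c lower (-0.76 ± 0.15), 1 each also when adjusted over the list alone (camera adjusted p = 0.516). Hnf4a lost its call without Lira161, Lira162, PBS155 or PBS157 and Serpina1c without Lira162 or PBS158, at adjusted p up to 0.122.

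Blood and immune cell markers gave few calls. Of 6 erythroid markers, Alas2 (-1.48 ± 0.28) and Klf1 (-1.08 ± 0.24) fell, 3 when adjusted over the list alone (camera adjusted p = 0.00323; adjusted p = 0.45 with an estimated correlation), and 3, 1, 1, 2, 0 and 0 did so without libraries Lira161, Lira162, Lira164, PBS155, PBS157 and PBS158. Alas2 lost its call without Lira164, PBS155, PBS157 or PBS158 and Klf1 without Lira162, PBS157 or PBS158 (adjusted p up to 0.109). Of 8 T and natural killer cell markers, Cd4 fell from 2.33 ± 0.45 to 0.60 ± 0.25 CPM (-1.97 ± 0.35, adjusted p = 0.0116) and Ccl5 rose, with 4 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.166; below 0.05 without Lira164, PBS155 or PBS157, at 0.0208, 0.048 and 0.0269, and 0.0109 without the filter). Of 13 markers of monocyte-derived macrophages, Cd9 rose (1.03 ± 0.21) and Spp1 fell, 2 and 1 when adjusted over the list alone (camera adjusted p = 0.0654 and 0.575 with an estimated correlation), with Cd9 not called without Lira161, Lira162, PBS155 or PBS158 (adjusted p up to 0.0769). Camera called this list without Lira161, Lira162, PBS155 or PBS157 (adjusted p = 0.00741, 0.0375, 0.048 and 0.000962), without the filter (0.0232) and with limma-voom (0.0361). Dendritic cell and antigen presentation markers held no called gene among 11 (camera adjusted p = 0.019; adjusted p = 0.548 with an estimated correlation), H2-Aa being at 25.8 ± 7.15 against 15.4 ± 2.92 CPM (adjusted p = 0.0758) and H2-Eb1 at 18.5 ± 3.94 against 11.7 ± 2.99 (adjusted p = 0.0921). H2-Eb1 passed without PBS157 (0.0428), and both did with DESeq2 (0.00951 and 0.0284). None passed when adjusted over the list alone, 2 were called without PBS157 and 4 with DESeq2, and the camera call was lost without Lira164 or PBS158 (adjusted p = 0.103 and 0.0716). None of 6 B and plasma cell markers passed, nor when adjusted over the list alone (camera adjusted p = 0.885), with Igj at 0.36 ± 0.19 against 0.91 ± 0.34 CPM and Cd79b at 0.93 ± 0.11 against 0.65 ± 0.49. Plin4 (1.81 ± 0.32), Fabp4 (1.44 ± 0.34) and Cidec rose among 10 adipocyte markers, 3 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.367), with a median of -0.04 and a mean of 0.13, and these 3 also stand in the lipid droplet list. The left-out libraries gave 0, 0, 3, 0, 0 and 1 of them, 3 others fell without Lira164, and none rose without the low-count filter. Cidec and Fabp4 were called only without Lira164, and Plin4 only without Lira164 or PBS158 (otherwise adjusted p up to 0.135). Neutrophil, acinar and muscle markers were tested for 1, 2 and 1 genes, with Csf3r at 0.00, Cela1 at -0.95, Cela2a at -0.07 and Mylpf at 0.57 on the log2 scale, none past the test over all genes. Adjusted over the list alone, 1 of the 2 acinar markers, Cela1, was lower. Cela1 passed without PBS157 (adjusted p = 0.0104) and with DESeq2 (0.00452).

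Immediate early genes, which respond within minutes to stimulation or tissue handling, were higher where they changed. Of 16 tested, 7 rose and none fell, 8 when adjusted over the list alone (camera adjusted p = 6.02e-08; adjusted p = 0.241 with an estimated correlation). Junb (0.99 ± 0.17), Ier2 (0.68 ± 0.14), Klf2 (0.83 ± 0.18) and Klf6 (0.57 ± 0.13) were among them, and their number was 2, 2, 7, 7, 1 and 1 without libraries Lira161, Lira162, Lira164, PBS155, PBS157 and PBS158. Junb lost its call without Lira161 (adjusted p = 0.0508), Ier2 without Lira161, PBS157 or PBS158, Klf2 without Lira161, Lira162, PBS157 or PBS158 and Klf6 without Lira162, PBS155, PBS157 or PBS158 (up to 0.122). Counts were also summed over all genes of the list, tested or not, and scaled to library totals without TMM factors. The sums were 528, 539 and 516 CPM in libraries Lira161, Lira162 and Lira164 and 348, 251 and 282 CPM in libraries PBS155, PBS157 and PBS158. Alb, the albumin gene, took between 4.07% (exact 95% interval 4.07 to 4.08) of counts in library Lira161 and 7.73% (7.72 to 7.74) in library PBS155, and the ribosomal RNA gene Rn45s between 0.258% (0.256 to 0.260) in PBS157 and 0.875% (0.871 to 0.878) in PBS155. These intervals cover counting error only.

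Several further lists held no called gene. Nuclear genes of oxidative phosphorylation had a median of -0.13 over 28 (camera adjusted p = 0.0422; adjusted p = 0.726 with an estimated correlation), with Sdha at 382 ± 27.5 against 486 ± 32.7 CPM and Sdhb at 133 ± 1.78 against 165 ± 16.7. That call was lost without Lira164, PBS157 or PBS158 (adjusted p = 0.193, 0.111 and 0.329), with library totals (0.0543) and with a mean CPM of at least 5 (0.0591), and 2 members fell without PBS155. Sdhb passed in that fit (0.0466) and Sdha with DESeq2 (0.0275). Cytosolic ribosomal protein genes had a median of 0.21 over 29 (camera adjusted p = 0.000546; adjusted p = 0.675 with an estimated correlation), with Rpl5 at 64.8 ± 4.40 against 48.3 ± 6.61 CPM and Rpl3 at 163 ± 30.2 against 119.9 ± 14.5; camera lost it without PBS155 (adjusted p = 0.0926), and 1 member rose without Lira164 and 1 without PBS157. That member was Rpl5 (adjusted p = 0.044 and 0.0408), which also passed with library totals (0.0337), without the filter (0.0374), with a mean CPM of at least 5 (0.0491) and with DESeq2 (0.0294). Rpl5 overlaps exons of Fam69a by 953 bp on the opposite strand, so its value is uncertain. Cell cycle genes had a median of 0.07 over 21 (camera adjusted p = 0.421), with Mcm6 at 4.22 ± 0.28 against 2.33 ± 0.74 CPM and Rrm2 at 4.66 ± 0.33 against 2.89 ± 0.96; 1 rose without PBS158, Rrm2 (0.0486), and 2 with DESeq2, among them Mcm6 (0.0351). None of the members of these 3 lists passed when adjusted over the list alone. Glp1r, the gene of the receptor that liraglutide binds, had 0 counts in each of the 6 libraries, which allows up to 0.111 CPM in library PBS155 and up to 0.144 CPM in library Lira161, taking 3 counts as the limit, so it was not detectable at this depth.

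Across the 41 lists with at least 5 tested genes, camera called 20 with the preset correlation, 9 upward and 11 downward, and 0 with an estimated correlation. With the estimate the smallest unadjusted camera p was 0.0149, for lipid droplets. Cholesterol synthesis, with 22 of 25 members lower, had 0.0275. The correlation was estimated from 6 libraries only, so these 0 calls do not show that no list moved. Fry, whose directional p tests whether the genes of a list move, on balance, one way and whose mixed p tests for change in either direction, called 6 and 34 lists; neither compares a list with other genes. Fry's directional calls were cholesterol synthesis (adjusted p = 0.0499), lipid droplets (0.0393) and 4 lists at 0.0325 each. Those 4 were PPAR-alpha targets with fatty acid oxidation, heat shock, T and natural killer cells and immediate early genes.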

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

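The alternatives described here were chosen before the data were examined. The count of 1107 changed genes stayed within 1.5 times under every alternative that used all 6 libraries (RLE 1101, upper quartile 1085, library totals 1065, no filter 1201, a mean CPM of 5 972, limma-voom 1136, without the 10 most abundant genes 1127, DESeq2 1623, with 3 adjusted p not given), and no changed gene turned its direction. The number with a log2 fold change of at least 1 fell from 383 to 246 with a mean CPM of 5, where 9262 genes were tested. Leaving out 1 library gave 393 to 1496 changed genes, about 160 to 694 higher, 231 to 802 lower and 184 to 549 with the larger change. Fewer libraries can give fewer calls, but without library Lira164 the count rose to 1496, and the cause was not tested. Of the 106 named genes that were called, 39 kept the call in all 6 such fits, with 54 to 96 called per fit, and 90 did so without the filter. Camera called 20 lists with the preset and 0 with an estimated correlation. Fry, which tests another hypothesis, called 6, of which T and natural killer cells were not among the 20. 15 of the 20 kept the camera call whichever library was left out, and oxidative phosphorylation, urea cycle, ribosomal protein, cholangiocyte and dendritic cell lists did not. Results that were not called also turned direction, and the cause was not tested: Csf3r, with a log2 fold change of 0.0040 with upper quartile factors, 0.040 with library totals, 0.061 with limma-voom, 0.053 without Lira162 and 0.44 without PBS155 (range with 1 library left out -0.22 to 0.44), Cela2a (0.21 without Lira162, 0.27 without PBS157; -0.35 to 0.27), Irs2 (-0.066 without Lira164; -0.066 to 0.82) and Col1a1 (0.22 without PBS157; -1.09 to 0.22). Camera's direction turned, at these adjusted p, for the periportal list (0.84 with no filter, 0.971 with limma-voom, 0.914 without the 10 most abundant genes, 0.253 without Lira164, 0.958 without PBS157, 0.822 without PBS158; range 0.253 to 0.958) and the glycolysis list (0.855 with limma-voom, 0.596 without PBS155, 0.678 without PBS157; range 0.185 to 0.968). It also turned for the lipoprotein list (0.883 without Lira161, 0.79 without PBS157; range 0.557 to 0.883), the NRF2 list (0.968 without Lira164; range 0.238 to 0.968), the B cell list (0.944 without Lira164, 0.587 without PBS155; range 0.557 to 0.944) and the extracellular matrix list (0.86 without PBS158; range 0.0422 to 0.86). No paired analysis was possible because the columns carry no triplicate number, so the replicate block and the correlation of same-numbered libraries were not run.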

Other observations

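The scan of gene families and the tests of the endothelial, clock-time and depth explanations were chosen after the results were seen; the splits of the libraries and the test of feeding state were not. Genes named in the first paragraphs were chosen after their values were seen. Some families of enzyme genes held several members that were lower after liraglutide, a few of them also in the fixed lists (Ces2a, Aldh1a1 and Akr1d1). Among 445 families formed from the roots of gene symbols, 7 of 14 tested carboxylesterase (Ces) genes fell, among them Ces2e (-1.13 ± 0.11, edgeR adjusted p = 0.00272) and Ces1g (-1.87 ± 0.34, adjusted p = 0.0252), and none rose (camera adjusted p = 3.23e-11; adjusted p = 1 with an estimated correlation). Of 16 Aldh genes 5 fell and 1, Aldh3a2, rose (0.94 ± 0.13, adjusted p = 0.00508), with a median of -0.23 (camera adjusted p = 0.000377; adjusted p = 1 with an estimated correlation). Of the 5 Aldh1 genes among them 4 fell, Aldh1b1 by 2.17 ± 0.13 (adjusted p = 0.000282), Aldh1l1 by 1.28 ± 0.12 and Aldh1a7 and Aldh1a1 by 1.00 ± 0.12 and 1.01 ± 0.19 (camera adjusted p = 2.88e-10; adjusted p = 1 with an estimated correlation). The sulfotransferase genes Sult1b1, Sult2a7 and Sult1d1 fell among 6, and 5 of 11 Akr1 genes fell. Reads of close paralogs may be divided between genes of these families, whose counts are therefore uncertain; with 1 library left out, Ces2c kept a log2 fold change between -2.88 and -2.37.

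Cyp26b1, whose product degrades retinoic acid, rose from 3.28 ± 0.29 to 19.7 ± 3.47 CPM (2.58 ± 0.16, adjusted p = 0.000313) and was the increase with the smallest p. Cyp2 genes were split, 10 of 32 lower and 2 higher, Cyp2c69 by 2.89 ± 0.28 and Cyp2c40 by 1.75 ± 0.28, 2 close paralogs (camera adjusted p = 0.00139; adjusted p = 1 with an estimated correlation). Of 7 tested Gimap genes, which are lymphocyte GTPases, Gimap3 (1.35 ± 0.25), Gimap1 (0.99 ± 0.22) and Gimap4 (0.71 ± 0.19) rose and none fell (camera adjusted p = 0.00921; adjusted p = 1 with an estimated correlation). Of 8 markers of T and natural killer cells 1 rose and 1, Cd4, fell (-1.97 ± 0.35), 4 and 1 when adjusted over the list alone (median 0.95), and of 19 endothelial markers 2 rose, 11 when adjusted over the list alone (median 0.74).

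The split of the 6 libraries by treatment gave 1107 changed genes, and the highest of the other 9 splits gave 0, so 1 of 10 splits gave as many. Camera with the preset correlation called 20 lists in the real split. The other 9 splits gave between 7 lists (Lira161, Lira164 and PBS158 against the rest) and 20 (Lira161, PBS155 and PBS158 against the rest). So 2 of 10 splits gave as many, and such a number of list calls was not particular to the split by treatment. Which lists were called, and in which direction, was not compared between the splits. Each of the other splits still holds the treatments in unequal numbers. With 10 splits no share under 0.05 can be reached.

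Of 19 endothelial markers 2 passed as higher (fry adjusted p = 0.156; camera adjusted p = 0.497 with an estimated correlation), with a mean level of 0.466 in PBS155 and 0.319 in Lira161, so the groups overlapped; a lower share of hepatocytes in the liraglutide pieces would raise markers of every other cell type alike. The endothelial level minus that of another class was compared between the groups. A class was taken to differ where the groups did not overlap and the difference exceeded 2 standard errors, a rule without a p-value. The difference was 1.02 ± 0.16 (SE, log2) for cholangiocytes, the first comparison made, and 0.70 ± 0.29 for B cells, so 2 of 7 classes passed this rule. For B cells, with 6 tested markers, the endothelial level minus the B cell level was 0.384, 0.454 and 1.27 in Lira161, Lira162 and Lira164. The B cell level itself was -0.065, 0.292 and -0.298 in these libraries. The difference was 0.12 ± 0.41 for Kupffer cells, 0.13 ± 0.35 for monocyte-derived macrophages, 0.13 ± 0.30 for T and natural killer cells, 0.25 ± 0.32 for dendritic cells and 0.26 ± 0.23 for stellate cells, whose medians were also above 0 (0.49, 0.55, 0.95, 0.47 and 0.36). Cholangiocyte markers did not rise, which such a share alone would not give, but their own call was lost without Lira161, Lira162 or PBS155. Erythroid markers, not among the 7 classes, were lower, with a median of -1.09 (camera adjusted p = 0.00323, and 0.45 with an estimated correlation). Adipocyte markers, also not among them, and B cell markers each had a median of -0.04. A lower share of hepatocytes, a change within endothelial cells and differences in tissue sampling may each play a part and stay open.

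Clock genes Per3 (-1.47, 95% interval -2.02 to -0.91) and Cry1 (-1.16, -1.61 to -0.71) fell, and a different time of day of collection between the groups is a candidate explanation. Nr1d1, with a log2 fold change of -0.13 (-0.41 to 0.15), and Nr1d2, with -0.15 (-0.39 to 0.08), did not move by the 0.5 this would predict, yet 2 times of day on either side of a peak can give like levels. Dbp, whose value is uncertain, changed by -0.75 (-1.34 to -0.17) and Arntl by 0.39 (-0.63 to 1.41). The labels give no time of collection, so this explanation and an effect of liraglutide cannot be told apart.

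The libraries of each group were spread along the axis that separates the groups, with library Lira164 nearest to PBS, and changed genes numbered 1496 without it. If mice differed in feeding state along that axis, differences between 2 libraries of a group should correlate across genes with the effect taken from the remaining libraries. An absolute r of at least 0.3, asked for in 4 of 6 such contrasts, was reached in 1 (0.393, Lira162 minus Lira164). The other liraglutide contrasts gave 0.178 (Lira161 minus Lira164) and -0.234 (Lira161 minus Lira162). The sign follows the order of subtraction, so the negative r places Lira162 farther along the effect than Lira161. The PBS contrasts gave 0.111 (PBS157 minus PBS158), 0.232 (PBS155 minus PBS158) and 0.136 (PBS155 minus PBS157). All were taken across 12626 genes, which are not independent replicates. Library depth followed the order along the first component in 0 of 2 groups, but 3 libraries per group exclude nothing. Both may play a part and stay open.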
